A study of Mus musculus with 6 samples.

How the data were processed

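Retinal cells of tamoxifen-treated mice of mixed C57BI6/S129 background were enriched with CD31 MicroBeads and profiled with the 10x Chromium 3' v3.1 assay, per the labels' protocols. Each of the 6 libraries pooled 4 retinas. The labels give 4 groups: P6 WT (1 library), P6 Alk5iEKO (1), P10 WT (2, named D7 and C7) and P10 Alk5iEKO (2, named B7 and E7). WT stands for tamoxifen-treated littermates that carry the floxed gene without Cre. Nothing in the labels says that libraries come from separate animals beyond the 4 retinas per library, so no p-value covers more than the spread between these samples.

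The deposited matrices hold raw, unfiltered UMI counts for 31053 genes and 6794880 barcodes per library, made by the authors with Cell Ranger (version 3.1.0 per the file headers) on mm10 per the submitters' processing notes. The annotation release behind them is not given in the sources used here. Coordinates come from GENCODE vM21 on GRCm38, in which 30934 of the 31053 gene identifiers were found, 30468 of them under the same symbol. Total UMIs were 97191133 in P6 WT, 91029955 in P6 Alk5iEKO, 99563036 in D7, 97720737 in C7, 116048101 in B7 and 100425093 in E7.

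Cells were called as barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs, with Python 3.11.15 and scanpy 1.11.5. This gave 5726 cells in P6 WT, 5506 in P6 Alk5iEKO, 9703 in D7, 5497 in C7, 6361 in B7 and 11045 in E7. Scrublet was set to an expected doublet share of 6% and marked 1.01%, 0.87%, 0%, 0.02%, 1.41% and 0% of them, so in D7, C7 and E7 it removed almost nothing. Log-normalised counts of all remaining cells were clustered with 3000 variable genes, 50 principal components, 15 neighbours and Leiden clustering at resolution 1.0, without integration. A cluster took the name of a cell class when at least 3 of that class's markers were at least 2 times the level of the other cells and at least 20 CPM, and the 10 leading genes were checked against it. Endothelial cells were clustered again with 2000 variable genes and 30 components. Sub-clusters with at least 2 markers of another class among their 10 leading genes against all other sub-clusters, or with a low UMI count, were left out. That last rule was set after the data were seen and applied once. Applied again against the kept sub-clusters, it would also leave out 518 cells with 3 haemoglobin genes among the leading genes (483 in B7, 25 in E7, 8 in P6 Alk5iEKO and 2 in D7). It removed 225, 193, 363, 272, 191 and 122 cells in the order P6 WT, P6 Alk5iEKO, D7, C7, B7 and E7, which is 87.9% of the endothelial class in D7 and 76.2% in E7 but 15.7% to 28.2% in the others.

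UMI counts were summed over the endothelial cells, or the cells of another class, of each library. RNA released from broken cells (ambient RNA) was estimated from barcodes ranked 20001 to 50000 by UMIs. In endothelial cells its share was read from neuron markers, so RNA of neurons in mixed droplets also counts as ambient. The estimated share of endothelial UMIs was 2.54%, 4.87%, 3.71%, 2.04%, 2.43% and 6.48% in the same order. CPM are counts per 1000000 UMIs of the summed class. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and F test), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. SE values are the absolute log2 fold change divided by the square root of the F statistic. The fit draws each gene's spread toward a trend shared by all genes. In endothelial cells the P10 fit had 2 residual and a median of 18.5 prior degrees of freedom. The fits over both ages and of age had 3 and 15.3. Most of the spread behind these p-values is therefore shared between genes and is not a gene's own spread between libraries. The comparisons were genotype at P10 (2 against 2 libraries), genotype over both ages with age as a term (3 against 3), age with genotype as a term (4 against 2), the interaction of genotype and age, and genotype at P10 in each other class with at least 20 cells in every P10 library. At P6, with 1 library per genotype, genotype was not tested on its own, and ratios carry 95% exact Poisson intervals. Shares of cells carry 95% exact Clopper-Pearson intervals, and P10 shares were compared by exact two-sided permutation tests, whose smallest p is 0.333. Intervals and lower limits of detection, set at 3 counts, cover counting error only.

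The comparisons, the gene lists, the rule for named genes and the rules for cells and classes, apart from the one on endothelial sub-clusters, were set before the data were examined. The rule for named genes took, for each tested comparison, up to 8 rising and 8 falling genes with the largest log2 fold change among called genes with a mean of at least 20 CPM, no overlap between groups and an ambient share of at most 20%. Gene models without a proper name and ribosomal, mitochondrial and haemoglobin genes were left out. It also took the receptors Tgfbr1, Tgfbr2, Acvrl1 and Eng, up to 4 members with the smallest p from each list, and up to 8 genes each way by ratio at P6 with at least 50 UMIs. Genes named outside it were chosen after their values were seen. They include Tgfbi as a marker of WT-like cells, Eda2r and other named p53 targets, and leading genes of clusters. Skil, Phlda3 and Cdkn1a are taken by the rule. Their use as a marker of WT-like cells (Skil) or as genes that led to the list of p53 targets was also chosen after their values were seen. A few genes that the rule takes are not reported here. The 35 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and at P6 by the percentile of a list's median among 10000 random lists drawn from 20 expression bins. Called members are counted over all genes tested and adjusted over the list alone. The lists of capillary and barrier genes share members, as do those of venous and fenestration genes.

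The tests were tried on simulated data. In these all genes shared a common dispersion, while real genes differ in spread, so recovery in the real data may be lower. Changed genes had a mean of at least 20 CPM. Of 200 changed genes, 100 were changed 4-fold and 100 were changed 2-fold. At 4-fold the P10 fit recovered 99% of its 100, the fit over both ages 100%, the age term 100% and the interaction 63%. At 2-fold these shares were 45%, 67%, 60% and 5%. For the other classes at 2-fold they were 5% in microglia, 67% in rods, 97% in bipolar cells, 0% in astrocytes and 7% in other leukocytes. Alternatives tried were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, leaving out each library, 500 or 2000 UMIs per cell, a mitochondrial limit of 10%, doublets kept, resolutions 0.5 and 2.0, ambient genes left out, thinned counts, equal cells per library, and proliferating cells left out. A further 7 were added after seeing the data: the 6% of cells with the highest doublet score removed, mixed sub-clusters kept, the rule for mixed sub-clusters applied again, a block for yield, both low-yield libraries left out, clusters from centred values, and tip markers counted after thinning. Tests within tip cells were not run, since some libraries held fewer than 20.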

Results

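The data are single-cell RNA counts from mouse retinas taken on postnatal day 6 (P6) or postnatal day 10 (P10), in 6 libraries of the 10x Chromium 3' assay. Each library pooled cells of 4 retinas after enrichment with CD31 beads, which bind endothelial cells, the cells that line blood vessels. Alk5iEKO pups carry a tamoxifen-induced, endothelial deletion of Tgfbr1, the gene of the TGF-β type I receptor ALK5, and tamoxifen-treated littermates without Cre served as WT controls. The 4 groups were P6 WT and P6 Alk5iEKO with 1 library each, P10 WT with 2 libraries (D7 and C7) and P10 Alk5iEKO with 2 libraries (B7 and E7). Total depth ranged from 91029955 to 116048101 unique molecular identifiers (UMIs) per library. Endothelial cells numbered 896 in P6 WT, 698 in P6 Alk5iEKO, 50 in D7, 691 in C7, 1025 in B7 and 38 in E7. Their summed UMIs were 18845816, 17878294, 810729, 10531590, 24856885 and 326772 in that order. D7 and E7 therefore limit the precision of every P10 value for endothelial cells.

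Endothelial cells were 15.8% of called cells in P6 WT (95% exact binomial interval 14.9 to 16.8) and 12.8% in P6 Alk5iEKO (11.9 to 13.7). At P10 they were 12.6% in C7 and 16.3% in B7, but 0.515% in D7 and 0.344% in E7, which are called the low-yield libraries from here on. Under the main setting rods, the photoreceptors of dim light, were the most numerous class in all 4 P10 libraries. They held 59.7% of cells in D7, 43.7% in C7, 26.6% in B7 and 55.6% in E7. They were 0.794% and 0.751% at P6. In B7 the order turned under alternatives, such as 437 rods and 1525 microglia at resolution 0.5, and 106 rods and 948 microglia at a mitochondrial limit of 10%. Microglia, the resident macrophages of the retina, were 24.3% of cells in B7 and 7.75% in E7, against 4.6% in C7 and 4.98% in D7. The P10 means were 16% ± 11.7 (SD, n = 2) in Alk5iEKO and 4.79% ± 0.265 (SD, n = 2) in WT, with p = 0.333 in an exact two-sided permutation test. That is the smallest p that groups of 2 and 2 libraries can give, so no share could pass a threshold of 0.05. At 2000 UMIs per cell the microglia class held 199 cells in B7, 171 in E7, 197 in C7 and 103 in D7. The main setting had 1526, 856, 253 and 483 in that order, so the excess in Alk5iEKO depends on the setting. The limit itself does not account for the loss in B7. Under the main setting, a microglial cluster of 1091 cells, 692 of them in B7, had a median of 18704 UMIs. Summed microglial UMIs in B7 fell from 21003181 to 2754820. Cells above the limit thus also left the class when cells were clustered and named again. The endothelial means, 8.34% ± 11.3 in Alk5iEKO and 6.54% ± 8.53 in WT (SD, n = 2 each), differed by less than the spread between replicates (exact permutation p = 1). Endothelial sub-clusters that met a rule for mixture with another class, or for low UMIs, were left out, and the rule was set after the data were seen. They held a further 3.74% of cells in D7, 1.1% in E7, 4.95% in C7 and 3.05% in B7. The shares describe bead-enriched libraries and need not match the tissue.

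**Figure D1:**
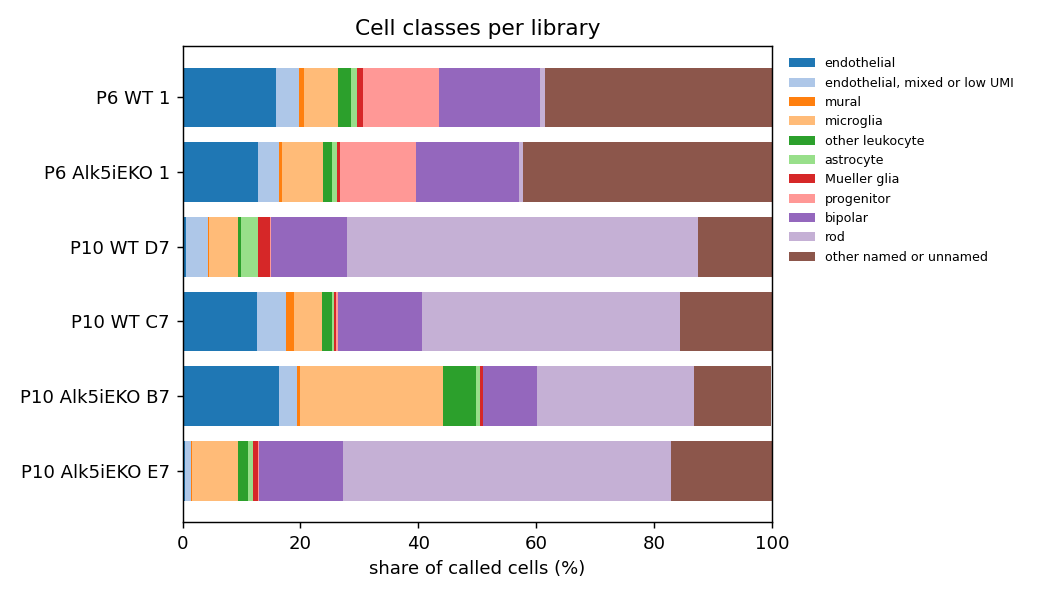
Share of called cells (%, horizontal axis) that each cell class held in each of the 6 libraries (bars). Endothelial cells were 12.6% to 16.3% of cells in 4 libraries and 0.515% and 0.344% in the low-yield libraries D7 and E7.

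The receptor that the deletion targets was examined first. Tgfbr1 (ENSMUSG00000007613, chromosome 4, 47353222 to 47414931, plus strand, GRCm38) measured 17.4 CPM (counts per 1000000 UMIs; 95% exact Poisson interval 15.5 to 19.3) in endothelial cells of P6 WT and 20.4 CPM (18.4 to 22.6) in P6 Alk5iEKO. At P10 it measured 32.1 CPM (20.9 to 47.0) in D7, 20.6 CPM (18.0 to 23.5) in C7, 20 CPM (18.3 to 21.8) in B7 and 24.5 CPM (10.6 to 48.2) in E7. Its log2 fold change at P10 was -0.23 ± 0.32 (SE, n = 2 and 2, adjusted p = 0.902), and the sign turned without D7 (0.01) or without B7 (0.05). Reads of a 3' assay need not come from the deleted part of the gene, so these counts do not measure the deletion. Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116084293 to 116175360, minus strand), the type II receptor that pairs with ALK5, rose at P10 from 216 CPM in both WT libraries to 325 CPM in B7 and 419 CPM in E7. Its log2 fold change was 0.76 ± 0.21 (SE, adjusted p = 0.0283; 0.77 and not called with the rule for mixed sub-clusters applied again), and at P6 it measured 121 CPM in WT and 330 CPM in Alk5iEKO. Acvrl1, which encodes the BMP9 and BMP10 receptor ALK1, had a log2 fold change of -0.07 ± 0.20 (adjusted p = 0.973), which turned to 0.07 without B7 and 0.06 without proliferating cells. At P6 it measured 98.4 CPM (94.0 to 103) in WT and 179 CPM (172 to 185) in Alk5iEKO. Eng, its co-receptor endoglin, had one of 0.02 ± 0.20 (adjusted p = 0.996), which turned to values between -0.30 and -0.02 under several alternatives.

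The comparison of endothelial cells between P10 Alk5iEKO and P10 WT asks what loss of ALK5 changes in retinal vessels. Among the genes with the largest falls in the Alk5iEKO libraries were Fbln5, Mfap2 and Eln. Fbln5 (ENSMUSG00000021186, chromosome 12, 101746565 to 101819055, minus strand), which encodes the elastic-fibre organiser fibulin-5, measured 208 and 215 CPM in WT (D7 and C7) and 10.8 and 6.12 CPM in Alk5iEKO (B7 and E7). Its log2 fold change was -4.36 ± 0.27 (SE, n = 2 and 2, adjusted p = 3.5e-09, edgeR). Mfap2, a microfibril protein, fell by 4.71 ± 0.45 on the log2 scale (adjusted p = 8.58e-07) and Eln, which encodes elastin, fell by 4.12 ± 0.38 (adjusted p = 1.87e-06). Both had 0 UMIs in E7, where 3 counts are 9.18 CPM. Spock2 (ENSMUSG00000058297, chromosome 10, 60106219 to 60135198, plus strand), a matrix proteoglycan, fell from 1700 and 1540 CPM to 163 and 88.7 CPM (log2 fold change -3.59 ± 0.26, adjusted p = 4.83e-08). In B7, 3070 of its 4052 UMIs came from 149 cells in sub-clusters made up mainly of WT cells (WT-like cells, 867 CPM), and the other 876 cells measured 46.1 CPM. Pmepa1, a TGF-β target that dampens SMAD signalling, fell by 3.52 ± 0.41 (adjusted p = 0.00243), and Htra3, a secreted serine protease, fell by 3.50 ± 0.34 (adjusted p = 6.71e-05). Spsb1, a substrate adaptor of a ubiquitin ligase, fell by 3.72 ± 0.35 (adjusted p = 9.15e-07), and Ctsw, a cysteine protease, fell by 3.56 ± 0.35 (adjusted p = 3.82e-05). Spsb1 and Ctsw also had 0 UMIs in E7.

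Genes that rose in P10 Alk5iEKO endothelial cells included a membrane protein induced by interferon, a carbonic anhydrase and a chemokine receptor of venules. Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825, plus strand), the interferon-induced membrane protein, measured 4.93 and 1.99 CPM in WT and 118 and 88.7 CPM in Alk5iEKO (log2 fold change 5.52 ± 0.36, SE, n = 2 and 2, adjusted p = 7.42e-09). With the rule for mixed sub-clusters applied again it was 4.89 and not called (adjusted p = 0.103), with 0 UMIs in the 13 cells left in E7. Reads of Ifitm1 can be hard to separate from those of its close relatives. Galnt15, which starts O-linked glycosylation, rose by 5.45 ± 0.38 on the log2 scale (adjusted p = 1.67e-08). Car4, the carbonic anhydrase, rose from 19.7 and 8.07 CPM to 258 and 474 CPM (log2 fold change 5.06 ± 0.52, adjusted p = 0.00308). Ackr1, the decoy chemokine receptor of venules, rose by 4.43 ± 0.36 (adjusted p = 9.62e-08). Aqp1, a water channel, rose by 5.57 ± 0.88 (adjusted p = 0.0487). Itih5, a hyaluronan-binding protein, rose by 4.51 ± 0.31 (adjusted p = 1.57e-07), Nr5a2, a nuclear receptor, by 4.62 ± 0.38 (adjusted p = 1.2e-07), and A4galt, the enzyme that makes the glycolipid Gb3, by 4.62 ± 0.53 (adjusted p = 1.52e-05). For these 8 genes and the 8 that fell, the ratio at P6 lay on the same side as at P10. Within P10 the rule for named genes asks for groups that do not overlap, so both pairs of libraries had to lie on that side.

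**Figure D2:**
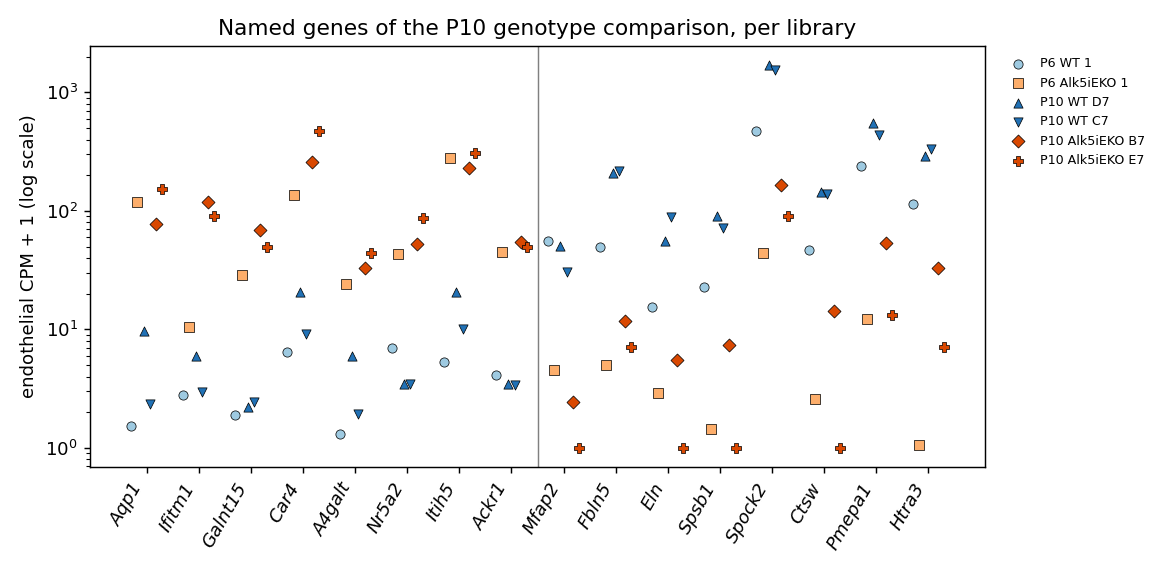
Endothelial CPM plus 1 (log scale, vertical axis) of the 16 genes with the largest called changes at P10 (horizontal axis), 1 point for each of the 6 libraries, P6 included. The genes were chosen among those whose P10 groups do not overlap, such as Fbln5 with 208 and 215 CPM in P10 WT and 10.8 and 6.12 CPM in P10 Alk5iEKO.

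Of 11582 genes tested at P10, 325 rose and 377 fell in Alk5iEKO endothelial cells, 702 in all, and 1692 had an unadjusted p under 0.05. The values of the 2 genotypes did not overlap for 699 of the 702, against 43.4% of all genes tested. Between the enriched libraries the genotypes also differed in sex: Xist, the RNA that silences an X chromosome, measured 872 CPM in C7 and 0.241 CPM in B7, and the Y-linked Ddx3y 0 and 84.8 CPM. D7 and E7 held both, with Xist at 630 and 845 CPM and Ddx3y at 51.8 and 45.9 CPM. The call count rests on leaving out sub-clusters mixed with another cell class or low in UMIs, a rule set after the data were seen. With these kept, edgeR called 0 genes (1379 with an unadjusted p under 0.05), although 701 of the 702 genes kept their sign. The rule compared each sub-cluster with all others. Against the kept ones alone, a sub-cluster of 483 cells in B7 and 25 in E7 had 3 haemoglobin genes among its 10 leading genes. Haemoglobin made up 240 CPM of it in B7, against 139 CPM in the other 542 cells and 9690 CPM in the ambient RNA. Without that sub-cluster (added after seeing the data) 615 genes were called, 481 of them among the 702, and all 685 of the 702 that were tested kept their sign, with 13 cells left in E7. The count was 294 with the DESeq2 test, 237 after thinning to the smallest library, 17 with the 6% of cells of highest doublet score removed (added after seeing the data) and 1333 with yield as a block (also added). In the setting that gave 17, cells were clustered again and E7 held 83 endothelial cells instead of 38. Their ambient estimate was 25.8% instead of 6.48%, so that setting changed more than doublets.

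The 35 gene lists were fixed in advance, and 32 had enough members tested at P10, of which limma's camera called 17. None of the 17 calls held with an estimated correlation, whose p is given beside each, and the directional test of fry called 0 lists (smallest adjusted p = 0.0581). Its test of change in either direction had an adjusted p under 0.05 for 15 of the 32 lists (smallest adjusted p = 0.00442). Of 16 genes of the response to TGF-β and ALK5, 8 fell and 1 rose over all genes tested, and 9 fell and 3 rose when adjusted over the list alone (camera adjusted p = 8.35e-10; adjusted p = 0.362 with an estimated correlation). Fn1, the matrix protein fibronectin, had a log2 fold change of -2.52 ± 0.22 and Skil, a feedback repressor of SMADs, one of -2.52 ± 0.26. Bambi, a pseudoreceptor that blocks TGF-β signals, and Ski, another SMAD repressor, fell by 1.39 ± 0.23 and 1.31 ± 0.22. Of 26 transporters and junction genes of the blood-retina barrier, 13 fell and 1 rose (16 and 2 adjusted over the list alone; camera adjusted p = 2.2e-15; adjusted p = 0.19 with an estimated correlation). Beside Spock2, Mfsd2a, the lipid transporter that restrains transcytosis, fell by 2.35 ± 0.22, and Tfrc, the transferrin receptor, fell by 2.97 ± 0.28. Cav1, the coat protein of caveolae and the riser of this list, had a log2 fold change of 1.76 ± 0.21. Of 10 capillary markers, 4 fell and 1, Car4, rose (5 and 1 adjusted over the list alone; camera adjusted p = 7.19e-08; adjusted p = 0.362 with an estimated correlation). The 4 with the smallest p, Spock2, Mfsd2a, Tfrc and the amino acid transporter Slc7a5 (-1.35 ± 0.22), are also on the barrier list.

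Of 22 genes of Norrin and WNT/β-catenin signalling, which drives barrier formation, 5 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00346; adjusted p = 0.376 with an estimated correlation). The transcription factor Foxq1 fell by 2.21 ± 0.24, β-catenin (Ctnnb1) by 1.15 ± 0.21, and the transcription factor Foxf2 by 1.03 ± 0.22. Of 20 tip cell genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00215; adjusted p = 0.635 with an estimated correlation). Mcam, an adhesion molecule, fell by 1.30 ± 0.22, Kcne3, a potassium channel subunit, by 1.77 ± 0.31 and Lamb1, a laminin chain, by 1.19 ± 0.24, while Esm1, a secreted proteoglycan of sprouting vessels, rose by 1.68 ± 0.36. Of 13 Notch genes, 4 fell (7 adjusted over the list alone; camera adjusted p = 0.00156; adjusted p = 0.646 with an estimated correlation), among them the receptor Notch1 (-0.74 ± 0.21) and the ligand Jag1 (-0.98 ± 0.27). Of 14 genes of VEGF receptors and angiogenic growth factors, 3 fell (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.635 with an estimated correlation). They were the receptors Flt4 (-1.05 ± 0.24) and Flt1 (-1.13 ± 0.26) and the growth factor Pdgfb (-0.88 ± 0.21), which recruits pericytes. Of 14 arterial genes, Fbln5 alone fell, also when adjusted over the list alone, 1 gene each way of counting (camera adjusted p = 0.0128; adjusted p = 0.771 with an estimated correlation).

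Of 16 genes of endothelial identity, 3 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.422 with an estimated correlation). Claudin-5 (Cldn5), the main protein of endothelial tight junctions, fell by 0.83 ± 0.22, and the sialomucin Emcn rose by 0.90 ± 0.20. At P6 Cldn5 lay the other way, with 1550 CPM in WT and 2870 CPM in the 690 Alk5iEKO cells outside the sub-cluster with haemoglobin genes. Of 23 genes of basement membrane and matrix, 6 fell and 4 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.0201, downward; adjusted p = 0.66 with an estimated correlation). Fn1 and the laminin linker Nid1 (-1.60 ± 0.21) fell, and the protease inhibitor Timp3 (2.02 ± 0.28) and the collagen chain Col15a1 (1.57 ± 0.23) rose. Of 10 genes of fenestration and permeability, 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0386; adjusted p = 0.759 with an estimated correlation). Esm1, the lipid phosphatase Plpp3 (1.43 ± 0.23) and Ehd4, a protein of endocytic membranes (1.28 ± 0.23), were among the 4, and Vwf, the clotting protein von Willebrand factor, fell by 2.16 ± 0.23.

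Of 15 interferon response genes, 7 rose and none fell (12 adjusted over the list alone; camera adjusted p = 2.23e-13; adjusted p = 0.19 with an estimated correlation). Ifitm3, a membrane protein that blocks virus entry, rose by 2.09 ± 0.23, and the antiviral proteins Bst2, Rsad2 and Isg15 rose by 1.43 ± 0.21, 2.92 ± 0.45 and 1.16 ± 0.24. Of 11 genes of class I antigen presentation, 7 rose (10 adjusted over the list alone; camera adjusted p = 1.13e-12; adjusted p = 0.19 with an estimated correlation). H2-K1, a class I heavy chain with near-identical relatives, rose by 1.92 ± 0.20, its light chain B2m by 1.72 ± 0.23, and the immunoproteasome subunits Psmb8 and Psmb9 by 1.59 ± 0.23 and 1.48 ± 0.27. Of 12 genes of inflammatory adhesion and chemokines, 3 rose (5 adjusted over the list alone; camera adjusted p = 0.000193; adjusted p = 0.527 with an estimated correlation). These were the chemokine Cxcl10 (3.98 ± 0.67), the macrophage growth factor Csf1 (1.03 ± 0.27) and the adhesion molecule Vcam1 (1.36 ± 0.37). Of 18 genes of G2 and M phase, 5 rose (14 adjusted over the list alone; camera adjusted p = 1.46e-08; adjusted p = 0.635 with an estimated correlation), such as cyclin B1 (Ccnb1, 1.21 ± 0.26) and the ubiquitin enzyme Ube2c (1.13 ± 0.24). Without proliferating cells these were 0.20 and 0.55 and neither was called, and Cenpe, another riser (0.91 ± 0.23), turned to -0.04. Of 17 genes of S phase, 3 rose (7 adjusted over the list alone; camera adjusted p = 0.000952; adjusted p = 0.759 with an estimated correlation), such as Gins2 of the replication helicase (1.09 ± 0.30; 0.75 and not called without proliferating cells). Of 17 genes of immediate early and dissociation stress, Ier3 (2.02 ± 0.26) and the phosphatase Dusp1 (0.94 ± 0.28) rose. That is 2 genes, with 3 adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.759 with an estimated correlation).

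The other 15 lists were not called at P10, with camera adjusted p between 0.0711 for the hypoxia response and 0.837 for bipolar cell markers. Of 17 receptors and SMADs of the TGF-β family, 2 rose and 2 fell (2 and 3 adjusted over the list alone), with Tgfbr3, the co-receptor betaglycan, at 3.19 ± 0.32 and the inhibitory Smad7 at -1.25 ± 0.32. Median, mean and test differed in sign for 4 lists. BMP and ALK1 response had a median log2 fold change of 0.44, a mean of -0.12 and an upward test. Venous genes had a median of -0.08, a mean of 0.18 and an upward test, with Ackr1 up and Vwf down. Mueller glia markers had a median of 0.01, a mean of -0.07 and an upward test, and glycolysis a median of 0.03, a mean of -0.17 and a downward test. No list of markers of other cells was called at P10, and all 10 rod markers tested had an ambient share over 20%. Of 6 microglia markers, 2 rose and 1 fell, and the risers, C1qa (2.53 ± 0.62) and Trem2 (2.92 ± 0.81), had all of their endothelial UMIs estimated as ambient (100%).

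**Figure D3:**
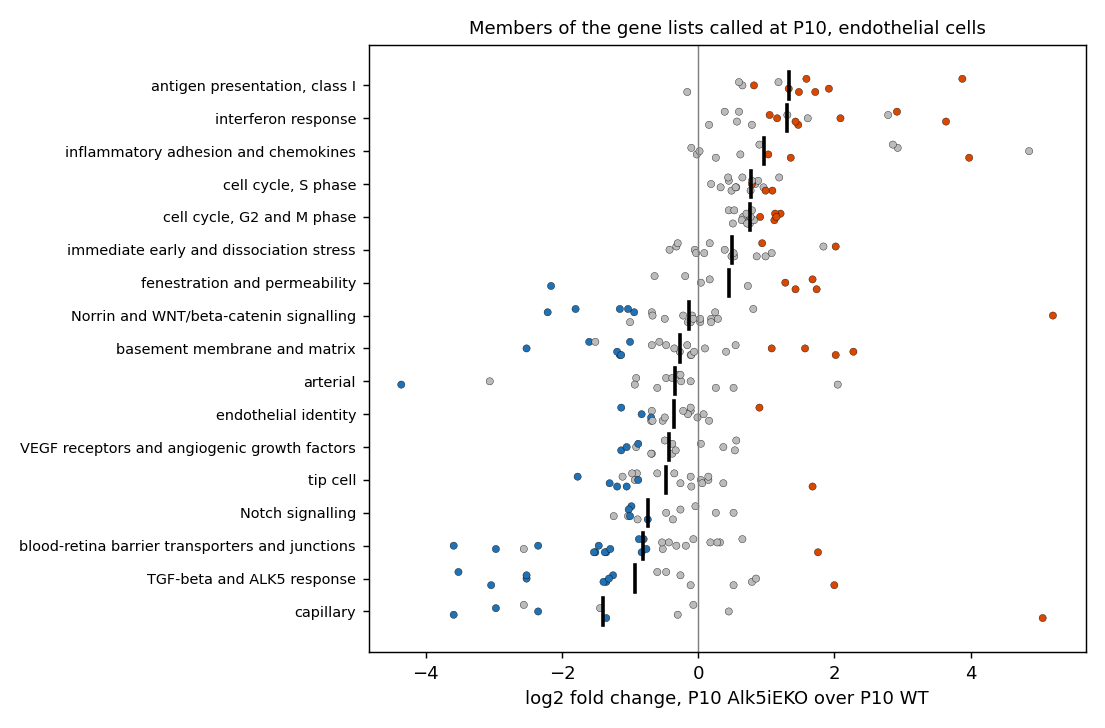
Log2 fold change of P10 Alk5iEKO over P10 WT endothelial cells (horizontal axis) for each tested member (points; orange rose, blue fell, grey not called) of the 17 lists called at P10 (vertical axis), with the list median as a black bar. Of 16 genes of the response to TGF-β and ALK5, 8 fell and 1 rose, and of 15 interferon response genes, 7 rose and none fell.

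With both ages fitted together and age as a term, 3 Alk5iEKO libraries were compared with 3 WT libraries to find changes shared by P6 and P10. The genes with the largest changes included Aqp1, Galnt15, Itih5, Car4 and Ackr1 on the rising side and Mfap2, Spsb1, Fbln5, Ctsw, Pmepa1, Eln and Spock2 on the falling side, all of which were also named at P10. Fbln5 had a log2 fold change of -4.10 ± 0.24 (SE, n = 3 and 3, adjusted p = 5.37e-09, edgeR) and Galnt15 one of 5.16 ± 0.30 (adjusted p = 5.37e-09). Genes named here and not at P10 were Iigp1, an interferon-induced GTPase (5.06 ± 0.38, adjusted p = 1.57e-06), Pcp4l1 (4.54 ± 0.39, adjusted p = 4.71e-05), Phlda3, a p53 target that restrains AKT (4.38 ± 0.43, adjusted p = 9.98e-05), and Ackr2, a scavenger receptor for chemokines (-3.61 ± 0.31, adjusted p = 4.36e-06). Of 12996 genes tested, 570 rose and 427 fell, 997 in all, and 2123 had an unadjusted p under 0.05. Values did not overlap for 831 of the 997, against 17.4% of all genes tested. The count was 190 with mixed sub-clusters kept and 197 with the 6% of cells of highest doublet score removed, both added after seeing the data, and 334 after thinning. Without both low-yield libraries it was 784, of which 700 were among the 997, and with the rule for mixed sub-clusters applied again 708, of which 683 were.

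At P6 there was 1 library per genotype, so ratios are given with 95% exact Poisson intervals that cover counting error only, and nothing was tested. All 16 interferon response genes measured had a ratio of Alk5iEKO over WT whose interval lay above 1, with a median log2 ratio of 3.65, at percentile 100 of 10000 random lists matched on expression (median 0.04). Isg15, a ubiquitin-like antiviral protein, measured 20.7 CPM in WT and 328 CPM in Alk5iEKO, a ratio of 15.8 (14.3 to 17.6). The ratio of Ifit3b, whose copy Ifit3 is near-identical so that reads can be shared, was 450 (80.4 to 17800), from 1 UMI in WT and 427 in Alk5iEKO. That of Ccl5, a chemokine that attracts T cells, was 390 (69.6 to 15400), from 1 and 370 UMIs. Class I antigen presentation (12 of 12 intervals above 1, median log2 ratio 1.59), inflammatory adhesion and chemokines (12 of 13, 1.70) and immediate early genes (15 of 17, 1.56) also lay at percentile 100. Fenestration and permeability genes had a median of 0.65 (percentile 99.94), but markers of other cells lay high as well, with mural cell markers at 1.02 (7 of 11 intervals above 1, percentile 98.82) and erythroid markers at 2.10 (4 of 4, percentile 99.14). Capillary markers had a median of -0.32 (percentile 0.12). G2 and M phase genes lay lower in Alk5iEKO, with 17 of 18 intervals below 1 and a median of -0.34 (percentile 0), as did S phase genes with a median of -0.29 (percentile 0).

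Among the 8 highest and 8 lowest ratios at P6, 7 belonged to genes on the X or Y chromosome. Alk5iEKO cells carried 1172 UMIs of Eif2s3y, 448 of Uty and 327 of Kdm5d, and WT cells 0 of each. Ddx3y had 1703 UMIs in Alk5iEKO and 1 in WT, and Xist 2 and 14155, while Tsix, whose reads cannot be told from Xist with certainty because it is its antisense RNA, had 2 and 591. The 2 P6 libraries thus differed in sex-linked transcripts as well as in genotype. Htra3 had 1 UMI in Alk5iEKO and 2154 in WT, a ratio of 0.000489 (1.24e-05 to 0.00273). Bgn, the X-linked proteoglycan biglycan, had a ratio of 0.0212 (0.0174 to 0.0256), Megf6 one of 0.0122 (0.00526 to 0.0243), Spsb1 one of 0.0206 (0.00882 to 0.0409) and Ncmap one of 0.031 (0.00994 to 0.0738). Efhd1 and Notum, a secreted WNT inhibitor, had 254 and 118 UMIs in Alk5iEKO and 0 in WT, where 3 counts are 0.159 CPM. Of 324 genes higher at P10 and measured at P6, 291 were also higher at P6, and of 377 lower at P10, 340 were also lower at P6. Their median log2 ratios at P6 were 1.65 and -0.85, beside medians of 1.66 and -1.43 at P10. The response to TGF-β and ALK5 had 7 intervals below 1 and 6 above among its 18 genes (median 0.06), and barrier genes had 15 below and 10 above among 26 (median -0.15). Some other lists called downward at P10 lay upward at P6. Endothelial identity had a median of 0.22 (10 intervals above 1 and 4 below), arterial genes 0.25, Norrin and WNT/β-catenin signalling 0.21, basement membrane and matrix 0.19 and VEGF genes 0.14. Notch genes (-0.16) and tip cell genes (-0.01) did not.

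The effect of age, P10 against P6 with genotype as a term, asks how retinal endothelial cells mature. Spock2 (log2 fold change 1.68 ± 0.24, SE, n = 4 and 2, adjusted p = 0.00156, edgeR), Slc22a8, an organic anion transporter of the barrier (1.27 ± 0.22, adjusted p = 0.00869), and Slco1c1, a thyroid hormone transporter (1.42 ± 0.24, adjusted p = 0.00869), rose with age. For Spock2 the 876 cells of B7 outside WT-like sub-clusters measured 46.1 CPM, against 43.1 CPM in such cells of P6 Alk5iEKO. Spock2 was itself a leading gene of the WT-like sub-cluster that held 102 of the 149 WT-like cells of B7. The split therefore sorts cells partly on Spock2 and cannot show where its rise in B7 comes from. Apoe, a lipid carrier, rose by 2.35 ± 0.32 (adjusted p = 0.00617), with an estimated ambient share of 12.7%, and Selenop, a selenium carrier, rose by 1.34 ± 0.23 (adjusted p = 0.00668). Pomc, Slc16a9, Cpe, Lurap1l and the growth hormone receptor Ghr rose by 1.89, 1.58, 1.28, 1.23 and 1.21 on the log2 scale. S100a6, a calcium-binding protein, fell by 2.23 ± 0.21 (adjusted p = 2.02e-05), and Lgals1, which encodes galectin-1, fell by 2.04 ± 0.23 (adjusted p = 0.000279), which turned to 0.07 with mixed sub-clusters kept. The chaperones Hsph1 and Hspd1 fell by 1.49 and 1.16, and Gchfr, Mettl16, Gnl3 and Sms by 1.44, 1.08, 1.06 and 1.05. Of 12996 genes tested, 81 rose and 42 fell, 123 in all, with 1626 at an unadjusted p under 0.05. Values did not overlap between the ages for 69 of the 123, against 16.8% of all genes tested. An ambient share over 20% was found for 17 of the 123. The count ran from 1 with mixed sub-clusters kept or with the 6% of cells of highest doublet score removed (both added after seeing the data), through 14 with equal cells per library and 27 after thinning, to 755 without B7. It was 673 without P6 Alk5iEKO, 214 without C7, 694 with no filter, 191 with the DESeq2 test, 62 at 500 UMIs, 53 at resolution 2.0 and 40 with the rule for mixed sub-clusters applied again (added).

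Camera called 16 of the 35 lists with age, and none held with an estimated correlation. The directional test of fry called 0, and its test of change in either direction 5 (smallest adjusted p = 0.0311). Barrier genes were called upward (3 of 26 rose over all genes tested and 7 adjusted over the list alone; camera adjusted p = 4.18e-07; adjusted p = 0.557 with an estimated correlation). Capillary markers were too (1 rose of 10, and 5 adjusted over the list alone; camera adjusted p = 8.27e-07; adjusted p = 0.557 with an estimated correlation). The response to TGF-β and ALK5 was called upward with 1 riser of 16 (Bambi at 1.11 ± 0.22; 5 up and 2 down adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.557 with an estimated correlation). Upward calls without any called member included 4 lists of signalling genes, each with adjusted p = 0.557 with an estimated correlation. They were receptors and SMADs of the TGF-β family (17 genes, 0 adjusted over the list alone, camera adjusted p = 0.0302) and BMP and ALK1 response (11 genes, 3 adjusted over the list alone, camera adjusted p = 0.0047). The others were Norrin and WNT/β-catenin signalling (22 genes, 2 adjusted over the list alone, camera adjusted p = 0.000858) and Notch (13 genes, 0 adjusted over the list alone, camera adjusted p = 0.0146). The arterial list was called upward with 1 riser of 14 (Fbln5 at 1.79 ± 0.23; 1 adjusted over the list alone; camera adjusted p = 0.000933; adjusted p = 0.557 with an estimated correlation). The venous list was called upward with 2 risers of 12 (among them Vwf at 1.75 ± 0.23; 2 adjusted over the list alone; camera adjusted p = 0.0146; adjusted p = 0.564 with an estimated correlation).

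Lists with a downward call began with S phase (0 of 17 genes, and 5 adjusted over the list alone; camera adjusted p = 5.73e-09; adjusted p = 0.557 with an estimated correlation). The others were G2 and M phase (0 of 18, and 0 adjusted over the list alone; camera adjusted p = 8.27e-07; adjusted p = 0.564 with an estimated correlation) and glycolysis (1 up and 1 down of 16, the same adjusted over the list alone; camera adjusted p = 0.00672; adjusted p = 0.564 with an estimated correlation). In glycolysis the enolase Eno1 fell by 1.0 ± 0.21 and Pfkfb3, which raises glycolytic flux, rose by 1.09 ± 0.24. Of markers of other cells, rod markers were called upward (1 of 10, and 6 adjusted over the list alone; camera adjusted p = 9.39e-13; adjusted p = 0.557 with an estimated correlation). So were bipolar cell markers (0 of 6, and 4 adjusted over the list alone; camera adjusted p = 1.48e-05; adjusted p = 0.557 with an estimated correlation) and cone markers (0 of 8, and 3 adjusted over the list alone; camera adjusted p = 0.000198; adjusted p = 0.557 with an estimated correlation). The last were mural cell markers (0 of 12, and 1 adjusted over the list alone; camera adjusted p = 0.00403; adjusted p = 0.574 with an estimated correlation). All 10 rod, 6 bipolar and 8 cone markers had an ambient share over 20% of their UMIs in endothelial cells. For the hypoxia response (median 0.20, mean -0.06, test upward) and mitochondrially encoded genes (median 0.12, mean -0.07, test downward), neither called, median, mean and test differed in sign.

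Whether the genotype effect itself differed between the ages was tested as an interaction, whose spread rests on the P10 replicates alone, so the p-values hold no spread between P6 libraries. The median prior degrees of freedom of this fit were infinite. For the typical gene the spread was therefore a trend shared by all genes, and the p-values do not measure that gene's own spread between P10 replicates. Sex goes with genotype at P6 (Xist at 751 CPM in WT and 0.112 CPM in Alk5iEKO) but not in the low-yield pair at P10, so the test does not separate age from sex. WT-like cells were 149 of 1025 in B7, 1 of 38 in E7 and 3 of 698 in P6 Alk5iEKO, which by itself makes genes lowered in the other Alk5iEKO cells look less lowered in B7 than at P6. No gene list was tested on it. The interferon-induced genes Isg15 and Ifit1 had interactions of -2.73 ± 0.39 (SE, log2, adjusted p = 1.09e-08, edgeR) and -3.99 ± 0.56 (adjusted p = 3.34e-09), a smaller genotype difference at P10 than at P6. Ifitm1, also induced by interferon, had one of 3.22 ± 0.58 (adjusted p = 3.11e-05), the other way. Cdkn1a, the cell cycle inhibitor p21, had a P6 ratio of 5.74 (5.40 to 6.11) and an interaction of -2.75 ± 0.37 (adjusted p = 8.6e-10). Ccnd2, a cyclin of G1 phase, had one of -3.25 ± 0.43 (adjusted p = 1.81e-10). Positive interactions included those of the linker histone Hist1h1b (2.40 ± 0.38, adjusted p = 6e-07), whose reads can be shared with its relatives, and of the spindle checkpoint kinase Bub1b (1.88 ± 0.45, adjusted p = 0.00836). Bub1b measured 65.4 CPM in WT and 46.6 CPM in Alk5iEKO at P6, and 17.3 and 17.0 CPM in WT and 46.4 and 27.5 CPM in Alk5iEKO at P10. Htra3 was lower in Alk5iEKO at both ages and more so at P6 (7.38 ± 0.69, adjusted p = 4.92e-22), where it had 1 UMI. Of 13712 genes tested, 40 had a positive and 78 a negative interaction, 118 in all, and 948 had an unadjusted p under 0.05. The count was 0 with mixed sub-clusters kept (520 at an unadjusted p under 0.05) and 0 with the 6% of cells of highest doublet score removed (267), both added after seeing the data. It was 19 with the DESeq2 test, 60 with no filter, 58 at resolution 2.0, 78 at resolution 0.5 and 191 without ambient genes. It was 55 without D7 and 52 without C7, and Mgp changed sign in both added settings.

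**Figure D4:**
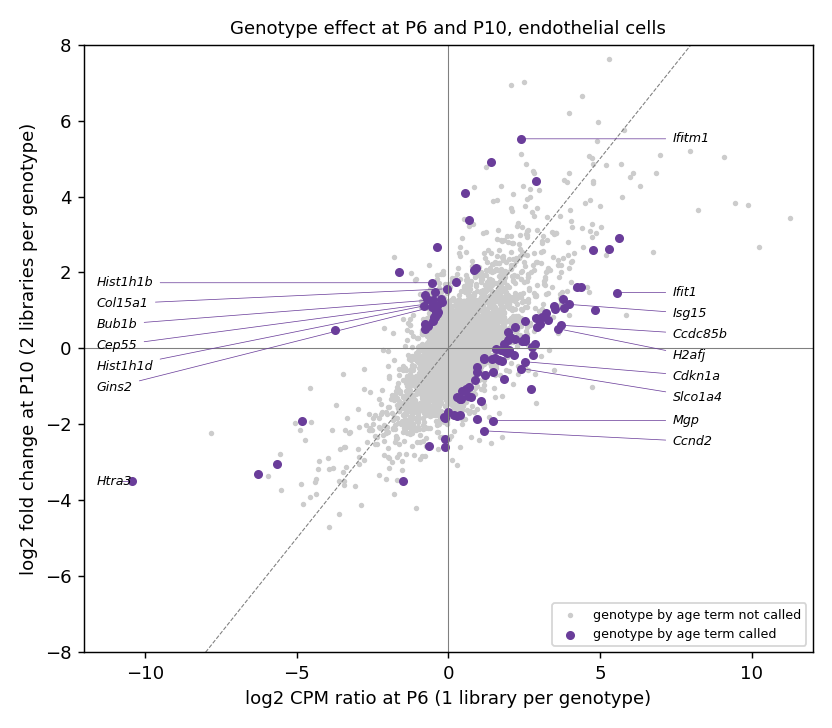
Log2 ratio of endothelial CPM at P6, Alk5iEKO over WT (horizontal axis), against the log2 fold change at P10 (vertical axis), 1 point per tested gene, purple where the interaction with age was called, with the named ones labelled and a dashed line of equal effects. Isg15 and Ifit1 lie below that line (interactions of -2.73 and -3.99) and Htra3 and Ifitm1 above it (7.38 and 3.22).

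Tip cells lead new vessel sprouts, and the study's title names them. A sub-cluster named from tip markers held 8 of 50 endothelial cells in D7 (16%, exact interval 7.17 to 29.1), 118 of 691 in C7 (17.1%, 14.3 to 20.1), 10 of 1025 in B7 (0.976%, 0.469 to 1.79) and 0 of 38 in E7, which allows a share of up to 7.89% at 3 counts and 9.25% by the exact interval. At P6 it held 1 of 896 cells in WT and 0 of 698 in Alk5iEKO. The P10 difference was -16.1 percentage points (p = 0.333, exact two-sided permutation test, the smallest possible). Because clusters followed genotype and age, cells were clustered again after centring each gene within its library and leaving out genes called between genotypes, a step added after seeing the data. The tip sub-cluster then held 7.92% of P6 WT, 7.45% of P6 Alk5iEKO, 20% of D7, 21.4% of C7, 10.1% of B7 and 10.5% of E7 cells, a P10 difference of -10.4 points (exact permutation p = 0.333). Cells with UMIs of at least 4 of 12 tip markers were 73.9% of P6 WT, 70.5% of P6 Alk5iEKO, 66% of D7, 60.6% of C7, 58.4% of B7 and 36.8% of E7 endothelial cells, a share that depends on depth. After thinning each cell to 2000 UMIs, a step added after seeing the data, it was 9.29%, 7.91%, 16.3%, 12.8%, 6.23% and 9.09% in that order, and 0 bipolar cells reached it. The P10 difference was -15.7 points before and -6.89 points after thinning (exact permutation p = 0.333 each). At resolution 2.0 the tip share was 5.41% in both D7 and E7, 24% in C7 and 3.34% in B7 (exact permutation p = 0.667). After thinning each cell to 1000 UMIs, Kcne3 was seen in 3.12% of P6 WT, 2.15% of P6 Alk5iEKO, 10.0% of D7, 3.91% of C7, 0.780% of B7 and 5.26% of E7 endothelial cells. Apln, a peptide of tip cells, was seen in 11.8%, 13.3%, 14.0%, 7.38%, 10.3% and 7.89%. In bipolar neurons, which should lack both, the shares were at most 0.105% and 0.528%, at median depths of 3561.5 to 6514.5 UMIs before thinning, against 4011.5 to 20958 in endothelial cells. Too few tip cells were present in some libraries for a test of their genes (under 20), so none was run.

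In the other cell classes at P10, edgeR called 0 genes between genotypes in microglia (339 at an unadjusted p under 0.05; DESeq2 0), rods (180; DESeq2 0), bipolar cells (282; DESeq2 2) and astrocytes (53; DESeq2 1). These classes pool clusters that differ between libraries: 1 cluster held 1403 of 1669 rods in B7 and 11 of 2401 in C7, and another 200 of 253 microglia in C7 and 272 of 1526 in B7. Leukocytes other than microglia had 5 genes that rose in Alk5iEKO and none that fell, of 6692 tested. Irf8, a transcription factor of dendritic cells and macrophages, measured 72.9 and 94.8 CPM in WT and 576 and 439 CPM in Alk5iEKO (log2 fold change 2.59 ± 0.32, SE, n = 2 and 2, adjusted p = 0.0346). Ccr9, a chemokine receptor, rose by 4.39 ± 0.42 (adjusted p = 0.0231), Mpeg1, a pore-forming protein of macrophages, by 4.64 ± 0.52 (adjusted p = 0.0273) and Lair1, an inhibitory receptor, by 3.88 ± 0.45 (adjusted p = 0.0273). Cox6a2 had 0 UMIs in both WT libraries, where 3 counts are 15.6 and 7.68 CPM, and 153 and 101 CPM in Alk5iEKO (adjusted p = 0.0273). A cluster led by Siglech, Cox6a2 and Ccr9, genes of plasmacytoid dendritic cells, held 49 of 6271 cells in B7 (0.781%), 30 of 11045 in E7 (0.272%), 1 of 9703 in D7 (0.0103%) and 0 of 5496 in C7. Irf8 was also among its 10 leading genes. It belonged to this pooled class, which numbered 357 cells in B7, 194 in E7, 39 in D7 and 97 in C7. The make-up of the class thus differed between genotypes, and these calls do not show a rise within a single cell type. The 5 calls were lost at 500 UMIs, where 5 other genes were called and only 2 of the 5 were tested, and at 2000 UMIs, at 10% mitochondrial share, with doublets kept, at resolution 2.0 and with the 6% of cells of highest doublet score removed. The count rose to 45 without D7, 11 without C7, 24 without B7 and 91 without E7, to 18 with DESeq2, 37 without ambient genes and 86 with no filter.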

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

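Of the tests in this part, those of sex, of ambient RNA, of both explanations for the WT-like cells and of Cre itself were chosen only after the result was seen, and so were the fits added after seeing the data.

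In endothelial cells, 118 genes passed the interaction test of genotype and age. Positive interactions (log2, the P10 effect minus the P6 effect) among the named genes were 7.38 for Htra3, 3.22 for Ifitm1, 2.40 for Hist1h1b, 2.05 for Hist1h1d, 1.88 for Bub1b, 1.81 for Cep55, 1.74 for Gins2 and 1.73 for Col15a1. Negative ones were -3.99 for Ifit1, -3.25 for Ccnd2, -3.25 for Mgp, -3.00 for Ccdc85b, -2.97 for H2afj, -2.83 for Slco1a4, -2.75 for Cdkn1a and -2.73 for Isg15. The spread in this test comes from the 4 P10 libraries, and for the typical gene from a trend shared by all genes. What another pair of P6 libraries would give is therefore not known. Sex goes with genotype at P6 and in 1 of the 2 P10 pairs, and WT-like cells were 14.5% of B7 but 0.43% of P6 Alk5iEKO, so a difference between ages is not separated from these here.

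The genotype difference in endothelial cells was weighed against chance, sex and RNA of other cells. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 997 called genes, and the highest of the others gave 0. Sex goes with genotype at P6 and in the enriched P10 pair but not in the low-yield pair, whose 2 libraries both hold cells with Xist and cells with Y-linked genes. There, 492 autosomal genes called in the other 4 libraries had a median log2 ratio of 1.56 in the direction seen in those, 108% of the 1.44 found there (95% bootstrap interval 101 to 115), and 473 had the same sign, which argues against sex as the whole cause. With genes of an ambient share over 20% left out, 894 genes were called against 702. Only 21 of the 702 had such a share, so leaving them out could remove few calls, and this test cannot decide on RNA of other cells. Its bound was also set after its result, and the call was lost with mixed sub-clusters kept. The genotype, which the design names, stays open as a hypothesis.

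In B7, 149 of 1025 endothelial cells (14.5%) fell into sub-clusters made up mainly of WT cells. They carried Skil and Tgfbi at 110 and 92.6 CPM, against 15 and 21.8 CPM in the other B7 cells and 133 and 97.2 CPM in WT-like cells of C7. Other genes lay between: Car4 at 77.9 CPM against 288 in the other B7 cells and 8.39 in C7, Ifitm1 at 10.2 against 136 and 1.98, and Spock2 at 867 against 46.1 and 1510. Cells or reads from another library would bring Xist, which stood at 0.565 CPM (95% upper limit 2.04) against 859 CPM in C7; this argues against the female WT libraries as their source, while a male sample outside these 6 was not tested. Incomplete deletion of Alk5 may account for them and could not be told apart from an undeleted-like state of deleted cells, since Tgfbr1 measured 20.9 CPM (74 UMIs) in these cells and 19.8 CPM in the others, from reads that need not lie in the deleted part.

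The interferon genes in P6 Alk5iEKO endothelial cells had a median log2 ratio of 3.65. A single sub-cluster of cells led by interferon genes is not the whole source, since 2.91 remained in the 286 Alk5iEKO cells outside it. A state of the whole sample may contribute: the median was 1.47 in microglia, 0.98 in astrocytes and 0.69 in bipolar cells, so neither bound set for an answer was met in all 3 classes. Other leukocytes, for which no bound was set, had a median of 1.22, with 10 of 10 genes higher. Activity of Cre itself cannot be told apart from loss of Alk5, because 0 libraries carried Cre with an intact Alk5 gene. Sex also goes with genotype at P6, while at P10 the low-yield pair, in which both libraries held both sexes, had a median log2 ratio of 1.41 over 12 genes in endothelial cells. In that pair it was 0.88 in astrocytes, 0.68 in other leukocytes, 0.37 in bipolar cells and 0.02 in microglia. For B7 over C7 it was 1.06 in endothelial cells and 2.33 in astrocytes (6 genes, 38 and 21 cells). Bipolar cells had 0.51, other leukocytes 0.24 and microglia -0.26.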

How the results depend on the processing

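The alternatives with the 6% of cells of highest doublet score removed, mixed sub-clusters kept, the rule for mixed sub-clusters applied again, yield as a block, both low-yield libraries left out, centred clusters and tip markers counted after thinning were chosen after seeing the data, and the others before. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The block for yield sets D7 with E7 and C7 with B7 by their yield, which is not a pairing given by the labels. Where leaving out a library left 1 in a group, edgeR took the spread from the other groups, so the lone library is assumed to vary like them. In endothelial cells depth limits E7 most, where 3 counts are 9.18 CPM, but in astrocytes it limits C7 (23.4 CPM) and in other leukocytes D7 (15.6 CPM). Alternatives for tests within tip cells were not run, since those tests were not.

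At P10, 702 genes were called between genotypes in endothelial cells, against 294 with the DESeq2 test, 237 after thinning to the smallest library (5009 genes tested), 17 with the 6% removed, 0 with mixed sub-clusters kept, 615 with the rule applied again (13 cells left in E7) and 1333 with the yield block, and 323 to 1117 without single libraries. Of the 702, 292 were among the 294, all 702 among the 1333, and 701 kept their sign with mixed sub-clusters kept (1379 genes at an unadjusted p under 0.05). In that setting the ambient estimate was 12.4% of endothelial UMIs in D7, 12.2% in C7 and 16.6% in E7. With the 6% removed it was 25.8% in E7, which then held 83 endothelial cells instead of 38. The main setting had 3.71% in D7, 2.04% in C7 and 6.48% in E7. The estimate is read from neuron markers, so it also counts RNA of the sub-clusters mixed with rods or bipolar cells that were kept. The cause was not tested. Over both ages 997 genes were called, against 197 with the 6% removed, 334 after thinning, 708 with the rule applied again and 190 with mixed sub-clusters kept. With age, 123 were called, against 694 with no filter, 191 with the DESeq2 test, 62 at 500 UMIs, 53 at resolution 2.0, 1 with the 6% removed, 27 after thinning, 14 with equal cells, 40 with the rule applied again, 1 with mixed sub-clusters kept, and 97 to 755 without single libraries. For the interaction, 118 were called, against 60 with no filter, 19 with the DESeq2 test, 78 at resolution 0.5, 58 at resolution 2.0, 191 without ambient genes, 0 with the 6% removed (267 unadjusted), 0 with mixed sub-clusters kept (520 unadjusted), 135 with the rule applied again (76 positive, against 40), and 52 to 158 without single libraries. Thinning and equal cells lower depth by construction, and for the rest the cause was not tested.

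In the other classes, microglia had 0 genes called, against 29 with no filter and 0 to 12 without single libraries. Rods had 0 to 45 without single libraries. Bipolar cells had 40 with no filter, 2 with the DESeq2 test, 1 at resolution 2.0 and 0 to 7 without single libraries, and astrocytes 25 with no filter, 1 with the DESeq2 test and 0 to 147 without single libraries. Other leukocytes had 5, against 86 with no filter, 18 with the DESeq2 test, 37 without ambient genes, 11 to 91 without single libraries, and 0 at 2000 UMIs, at 10% mitochondrial share, with doublets kept, at resolution 2.0 and with the 6% removed (edgeR, with 241 to 307 genes at an unadjusted p under 0.05). At 500 UMIs 5 were called, 0 of them among the first 5, of which 2 were tested. The lists called numbered 17 at P10 and 16 with age, and 0 in both with an estimated correlation and with the directional test of fry. The P10 difference in the tip share was -16.1 points, and -9.04 at resolution 0.5, -10.3 at resolution 2.0 (5.41% in both D7 and E7), -10.4 with centred clusters and -15.7 for cells with at least 4 of 12 tip markers, mostly from E7 (36.8%), with 60.6% in C7 and 58.4% in B7. That last share depends on depth, and the difference was -6.89 after thinning each cell to 2000 UMIs and -3.35 at 1000 UMIs. The cause was not tested for these.

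Signs turned for receptors that were not called. At P10, Eng (0.02) was -0.04 at 500 UMIs, -0.03 at resolution 2.0, -0.30 with the 6% removed, -0.10 without proliferating cells, -0.04 with equal cells, -0.07 with mixed sub-clusters kept and -0.04 to 0.14 without single libraries; Acvrl1 (-0.07) was 0.06 without proliferating cells and -0.13 to 0.07 without single libraries, Tgfbr1 (-0.23) -0.61 to 0.05 without single libraries, and the called Cenpe (0.91) was -0.04 without proliferating cells, which express it. Over both ages, Eng (0.04) was -0.01 at 500 UMIs, -0.19 with the 6% removed, -0.06 after thinning, -0.04 without proliferating cells, -0.01 without both low-yield libraries and -0.02 to 0.04 without single libraries; Acvrl1 (0.24) was -0.10 to 0.36 without single libraries; and Tgfbr1 (-0.07) was 0.01 without proliferating cells, 0.04 without both low-yield libraries and -0.25 to 0.04 without single libraries. With age, mixed sub-clusters kept gave -0.04 for Acvrl1 (0.30), -0.02 for Eng (0.21) and 0.07 for Lgals1 (-2.04), and Acvrl1 was -0.11 to 0.66 without single libraries. In the interaction, Eng (-0.03) was 0.03 with no filter, 0.05 at 10% mitochondrial share, 0.03 with the rule applied again and -0.09 to 0.07 without single libraries, and Mgp (-3.25) was 0.99 with the 6% removed and 0.15 with mixed sub-clusters kept. The cause was not tested. The values under alternatives for named genes, lists, tip marker shares and counts of genes called higher or lower were tallied. Of these, 2733 stayed the same, 634 kept direction and lost the call, 120 moved and 38 turned. Genes called in neither fit also count as the same. Of the counts of genes and lists called, the counts of P6 intervals, the class shares and the tip shares, 126 stayed the same and 67 moved.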

Other observations

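The test of p53 targets over both ages was planned before its result was seen, and that at P10 alone after it, on a list chosen after Cdkn1a, Phlda3 and Eda2r had been seen in the table of genes.

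Some clusters of macrophages and microglia held a larger share of called cells in both Alk5iEKO libraries at P10 than in both WT libraries, in shares that were not tested. A microglial cluster led by Slc7a11, Hmox1 and Srxn1, genes of the response to haem and oxidants, held 11% of cells in B7 and 2.26% in E7, against 0.091% in C7 and 1.28% in D7, and 0.348% and 0.0176% in P6 Alk5iEKO and P6 WT. A macrophage-like cluster led by Ms4a7, Pf4 and Cd36, which the naming rule left unnamed, held 6.46% in B7 and 2.11% in E7, against 0.455% in C7 and 1.0% in D7, and 1.63% and 0.529% at P6. The microglial cluster led by P2ry12 and Cx3cr1, genes of resting microglia, did not part the genotypes, with 4.34% in B7, 2.15% in E7, 3.64% in C7 and 1.5% in D7. A cluster of T and NK cell genes (Trbc2, Cd3d, Nkg7) held 2.95% in B7 and 0.96% in E7, against 0.728% in C7 and 0.268% in D7. A cluster of B cell genes (Igkc, Cd79a, Ms4a1) held 1.88% in B7 and 0.507% in E7, against 1.02% in C7 and 0.124% in D7, so E7 lay below C7. These genes and clusters were chosen after their values were seen.

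A few endothelial sub-clusters came mainly from Alk5iEKO libraries. One led by Ccl5, Cxcl10, Ifit3 and Rsad2 held 432 cells, 412 of them from P6 Alk5iEKO. A sub-cluster led by Ifitm1, Car4 and Galnt15, in which haemoglobin genes were also among the leading genes, held 518 cells, 483 of them from B7 and 25 from E7. Erythroid markers at P6 had a median log2 ratio of 2.10 in endothelial cells, with 4 of 4 intervals above 1.

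A hypothesis raised by Cdkn1a, Phlda3 and Eda2r was that targets of p53, the DNA damage and stress factor, rise together in Alk5iEKO endothelial cells. Over both ages, the 20 other members tested had a median log2 fold change of 0.89, and 6 rose and none fell, with a camera p = 1.17e-07 (p = 0.2 with an estimated correlation). These p-values stand for this list alone and were not adjusted. Gdf15, a stress cytokine, rose by 4.77 ± 0.71, Ccng1, a cyclin induced by p53, by 1.70 ± 0.28 and Bax, which opens mitochondria in cell death, by 0.98 ± 0.19, while Cdkn1a itself stood at 0.61 ± 0.80 (adjusted p = 0.917). The single P6 pair had larger values (median log2 ratio 1.45, 19 of 20 intervals above 1; ratio 20.8 for Dcxr and 8.05 for Trp53inp1, not called) than P10 alone, where the median was 0.50, 2 of 18 rose, and camera gave p = 0.00645 (p = 0.247 with an estimated correlation). Shared activation of p53 may be one reading, which the preset correlation favours and the estimated one leaves open.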
